A study of Homo sapiens with 4 samples.

How the data were processed

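Total RNA from Granta-519 cells was depleted of ribosomal RNA and made into libraries with an Illumina mRNA-Seq kit, per the labels' protocols. There were 4 libraries, 2 of cells with FGFR1 knockdown and 2 controls, grouped and numbered from the sample titles. Each deposited table gave, per the file headers, a count, an FPKM value and a TPM value for each of 51780 RefSeq transcript rows of 25680 gene symbols. The counts were whole numbers that the authors had not normalised, as the values show. In the authors' FPKM column, 100% of values implied a whole transcript length within 0.01 bases in every library, so it is the count per length and per column total. The authors' TPM column was the same measure rescaled to a fixed total. The genome build was hg19, per the submitters' processing notes. The aligner, the counter and the strand setting are not given in the sources used here, and FPKM and TPM were used only to check the units and lengths.

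Transcript rows of a gene each counted the reads they shared. Over 6475 genes with at least 2 transcripts of a mean count of 50 or more, the median transcript held 98.8% of the count of the highest. The design had assumed that transcript counts would be summed per gene, which would count reads several times, since summed totals came to 2.15 to 2.20 times those of 1 transcript per gene. Each gene was therefore given the counts of its transcript with the highest mean CPM over all 4 libraries, and the sum was run as an alternative. This change, the alternative with the longest transcript and the one without genes that have copy rows were chosen after seeing the data. The files held 4837 rows marked as further copies of a transcript, in 782 genes, and 0 rows that name no gene.

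The comparison was fitted with edgeR 4.0.16 in R 4.3.3 on counts, with TMM scaling (factors 0.950 and 0.959 for the controls, 1.04 and 1.05 for the knockdown libraries), filterByExpr at a minimum count of 10 and a minimum total of 15, robust dispersions and the quasi-likelihood F test with 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over 16088 genes and called below 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM values were scaled by the TMM library sizes, and errors beside them are SD over 2 libraries. The biological coefficient of variation was 16.1%. The chi-square per degree of freedom was 31.9 between the controls and 6.15 between the knockdown libraries, so neither pair looked like a single library deposited again. This does not show that the libraries came from separate cultures, since repeat libraries of 1 culture also differ by more than counting noise.

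Before the data were examined, 36 gene lists were fixed, of which 32 with at least 5 tested genes were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over those 32. Camera with an estimated correlation and fry were run beside it. The list of genes encoded in mitochondrial DNA matched 0 genes in the files. With the preset correlation 16 lists were called, and with an estimated correlation 0. The preset version takes its degrees of freedom from the number of genes, and the other from the 2 residual ones of the fit. The estimate was -0.0074 for S phase and -0.0105 for the respiratory chain, below the preset, so correlation did not raise their adjusted p. It was 0.228 for glycolysis and 0.552 for histones. Fry called each of the 16 lists in the same direction except the histone list, with adjusted p from 0.00143 to 0.0271 (0.0654 for histones). It asks whether the members changed, not whether they changed more than other genes. None of these tests shows whether a list would change again in separate cultures. The genes named in the report follow a rule set at the same time: FGFR1, the 6 largest rises and 6 largest falls among coding genes with a mean of at least 5 CPM in the higher group and separated libraries, the 2 called members of smallest adjusted p in each list described plus the largest change against its majority, and the 2 most abundant members of cell type and quality lists. Some genes that the rule names are not reported here. Coding genes were taken from the reference tables for GRCh38, in which the transcript of 25546 genes (99.5%) was found by identifier. As that build is not that of the files, no coordinates are given. XIST and Y-linked genes were left out.

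The scripts were tested on simulated counts for the 16088 genes with 200 changed. EdgeR recovered 0% of genes changed 1.5-fold, 22% at 2-fold, 54% at 3-fold and 60% at 4-fold, and 5.56% of its calls were false. DESeq2 gave 38.0% false calls and limma-voom 3.33%. That simulation drew dispersions around the fitted trend, and was adopted after a first one, with the dispersion estimated for each gene, had given 31 false among 156 edgeR calls (19.9%). Over 4 simulations of each kind the false share of edgeR calls was 1.85% to 7.69% around the trend and 12.5% to 19.9% with the dispersions of each gene. In such a setting the adjusted p can therefore understate the share of false calls. The simulations changed 200 genes, whereas 6524 were called in the data, and they gave both groups the same dispersion. Their recovery and false shares need not hold for these libraries. In the simulated set test the lowered set was called and 0 of 30 unchanged sets were.

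Alternatives fixed beforehand were median-of-ratios, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 1 CPM in 2 libraries, the replicate number as a block, transcripts tested separately, removal of histone, ribosomal RNA and small RNA genes, a glmTreat test against 1.5-fold, and each library left out in turn. In the last case the lone library of a group is assumed to vary like the other group. Where both controls had 0 counts, a fold is given against 3 counts in each library. It is not a firm bound, because the control pair spread more than counting error does (pooled variance-to-mean ratio 4.41 at 1 to 5 counts). Floors and SDs cover counting error and the spread between 2 libraries, and reads without molecular identifiers are not independent molecules.

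Reads of near-identical genes (paralogs, pseudogenes, HLA genes, histones, ribosomal protein and heat shock genes) could be split between copies, so single members of those families are uncertain. Among 83 named genes, 9 have a genomic span in GRCh38 that overlaps another gene with at least 10% of their counts. Whether exons overlap was not checked, and without a known strand setting reads from any shared exon cannot be told apart. Of these 9 genes, those reported here were ALAS2, ATP5S, CIITA, DNAJB1, IFIT2, NME1, SOD2 and TNFRSF10B. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.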

Results

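RNA sequencing measured transcript levels in Granta-519 cells, an established human line of mantle cell lymphoma, a cancer of mature B cells. FGFR1, which encodes a receptor tyrosine kinase for fibroblast growth factors, was knocked down with a short hairpin RNA in 2 libraries, and 2 control libraries were made beside them. The labels do not describe the control further, and nothing in them says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Reads counted at 1 transcript per gene came to 24218358 and 24727200 in the control libraries and 20084944 and 18280864 in the knockdown libraries. A count above 0 was found for 17535 and 17188 genes in the controls and for 19462 and 21336 genes after knockdown.

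The targeted gene was measured first in every library. FGFR1 (transcript NM_001174064) had 2014 and 2196 counts in the controls and 588 and 469 counts in the knockdown libraries. Its normalised level was 90.1 ± 3.62 CPM (SD, n = 2) in control cells and 26.3 ± 2.65 CPM (SD, n = 2) after knockdown, a 3.43-fold lower level. FGFR1 fell by 1.78 on the log2 scale (SE 0.11), with both knockdown libraries below both controls (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000192).

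The only comparison in the design asks how the transcriptome of these lymphoma cells differs when FGFR1 is knocked down. Genes of DNA replication and mitosis were lower nearly throughout, and so were most nuclear genes of the respiratory chain. With all 4 libraries most target genes of p53 and NF-kB, most genes of the amino acid response and most ribosomal protein genes were higher. Most ribosomal protein genes no longer passed without knockdown library 1 or 2, nor did most NF-kB targets without knockdown library 1. Calls over all genes also fell in those fits, as given below. In all, 6524 of 16088 genes tested changed, 2974 of them higher and 3550 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1530 were at least 2-fold higher and 954 at least 2-fold lower. In each of the 6524 genes both knockdown libraries lay on the same side of both controls, which passing the test nearly requires. Such a separation was seen in 73.2% of all genes tested, against the 33.3% that interchangeable libraries would give on average. Any difference between the groups besides FGFR1 would also raise the share seen. Of the calls, 45.6% were rises with the scaling used here, against 61.4% with upper-quartile scaling and 58.1% with library totals. Upper-quartile scaling and library totals moved the median of all genes to 0.17 and 0.14 on the log2 scale.

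The number of calls rested on the libraries in the fit, and each value given here without a library leaves out 1 library at a time. Without knockdown library 1 or 2, 2761 and 2678 genes passed, of which 1053 and 1093 were higher and 1708 and 1585 lower, while 9505 and 9391 passed without control library 1 or 2, with 4848 and 4661 of them higher. The calls of at least 2-fold became 683 and 692 higher without knockdown library 1 or 2, and 2557 and 2392 higher without control library 1 or 2.

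**Figure D1:**
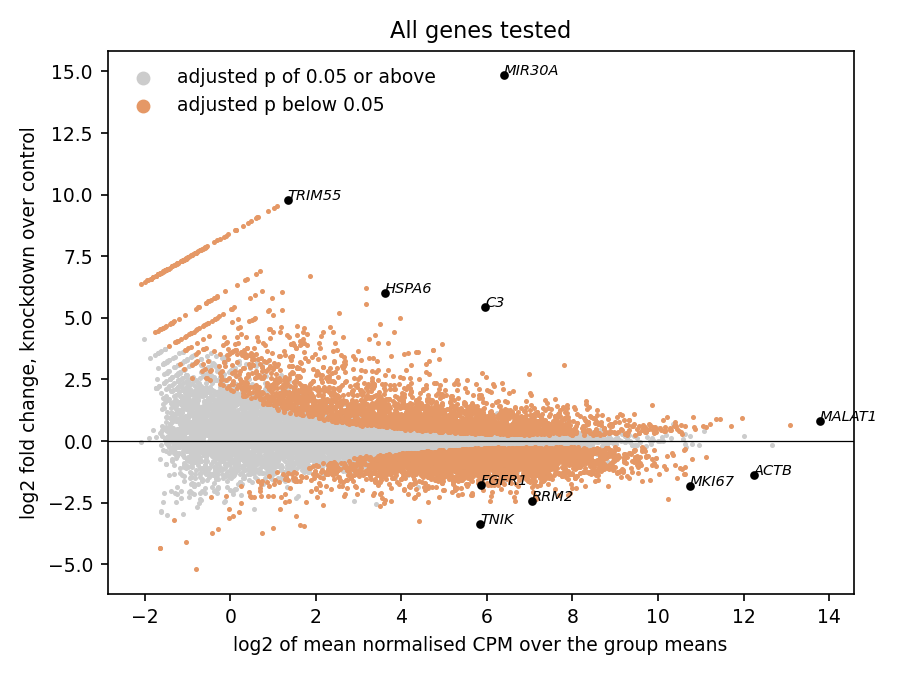
Log2 fold change of knockdown over control (vertical axis) against the log2 of the mean normalised CPM (horizontal axis) for every gene tested, with genes at an adjusted p below 0.05 in orange and 10 genes marked in black. FGFR1 lies at -1.78, and MIR30A stands apart at the top with no counts in either control library, where its fitted height is not a bound.

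The largest rises among coding genes were in genes with few reads in control cells. TRIM55, a muscle ubiquitin ligase, had 0 counts in both controls and 129 and 76 after knockdown, 39.4-fold higher against a floor of 3 counts per library. HSPA6, a stress-inducible heat shock protein, went from 13 and 4 counts to 522 and 442, a log2 change of 6.02 (SE 0.40) that became 7.09 and 5.42 without control library 1 or 2. EXPH5 rose by 5.56 on the log2 scale (SE 0.37), and by 6.33 without control library 1. C3, the central component of complement, rose from 2.78 ± 0.73 to 121.5 ± 2.89 CPM (SD, n = 2 each), a log2 change of 5.45 (SE 0.17), and the matrix protein gene HMCN1 rose by 4.73 (SE 0.25). UPB1, a pyrimidine catabolism enzyme, had 14 and 0 counts in the controls and 251 and 207 after knockdown, a log2 change of 5.21 (SE 0.87). For UPB1 the edgeR Benjamini-Hochberg adjusted p was 0.00733 with all libraries and 0.0625 with no filter on low counts. The log2 change was 4.24 without control library 2. Against 3 counts in control library 2 alone UPB1 was 89.9-fold higher, which is not a bound, since control library 1 had 14 counts.

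The largest falls among coding genes included a kinase and an adaptor of lymphocyte signalling. TNIK, a kinase of the Wnt pathway, fell from 104.1 ± 6.42 to 10.2 ± 1.30 CPM (SD, n = 2 each), a log2 change of -3.35 (SE 0.13). GRAP2, an adaptor protein of immune receptors, fell by 3.23 on the log2 scale (SE 0.18), and the matrix protein gene SPARC fell by 2.63 (SE 0.21). The transcription factor gene TSHZ2 had a log2 change of -3.43 (SE 0.48). SEMA5A, a semaphorin gene, had a log2 change of -3.39 (SE 0.77), which was -2.51 without knockdown library 1 and -5.79 without knockdown library 2.

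Cell cycle genes fell as a group. Of 39 genes of DNA replication and S phase, 38 fell and 0 rose, with a median log2 change of -1.34, and all 34 genes of mitosis fell, with a median of -1.35. The counts were the same adjusted over the list alone. RRM2, the small subunit of ribonucleotide reductase, fell from 224.4 ± 6.22 to 41.6 ± 4.98 CPM (SD, n = 2 each), 5.39-fold lower. CCNB1, the cyclin of mitotic entry, fell by 1.74 (SE 0.08), and DLGAP5, a spindle protein gene, fell by 1.81 (SE 0.09). Camera with a preset correlation takes genes as its units, so its adjusted p does not measure whether the fall would recur in separate cultures. That test gave an adjusted p of 1.28e-39 for S phase and 1.68e-43 for mitosis, and the adjusted p was 0.0703 for each with an estimated correlation. Replication-dependent histone genes moved with them: 42 of 61 fell, 0 rose and 46 fell adjusted over the list alone, with 25 falling without knockdown library 1 (camera adjusted p = 8.73e-20; adjusted p = 0.367 with an estimated correlation and 0.0654 with fry). HIST1H4H and HIST1H2BI had log2 changes of -1.84 (SE 0.09) and -1.75 (SE 0.09), and the most abundant, HIST1H1B and HIST1H1E, of -1.58 (SE 0.11) and -0.96 (SE 0.17). Histone genes took 1.79% and 1.40% of counts in the controls against 0.675% and 0.788% after knockdown.

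Target genes of p53, a transcription factor of the DNA damage response, were mostly higher: 21 of 28 rose and 0 fell, also adjusted over the list alone, with a median log2 change of 0.92. ZMAT3, an RNA-binding protein gene, rose 3.04-fold (log2 1.61, SE 0.07) and the death receptor gene TNFRSF10B rose 2.57-fold (log2 1.36, SE 0.07). The camera adjusted p was 3.99e-13, and the adjusted p was 0.110 with an estimated correlation. Of 17 genes of the BCL2 family 4 rose and 3 fell, with 5 and 3 adjusted over the list alone, and the camera test did not call the family (adjusted p = 0.337). BCL2, which holds back apoptosis, rose from 496.8 ± 18.4 to 1370 ± 23.7 CPM (SD, n = 2 each), and PMAIP1, which promotes it, rose by 1.26 on the log2 scale (SE 0.13). The proapoptotic BIK was 2.83-fold lower, with an edgeR Benjamini-Hochberg adjusted p of 0.0195 that became 0.111 and 0.179 without knockdown library 1 or 2. Without either of those libraries 2 members of the family rose, and 7 rose without control library 2, while 1 fell without knockdown library 1. With upper-quartile scaling 8 rose and with library totals 7.

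**Figure D2:**
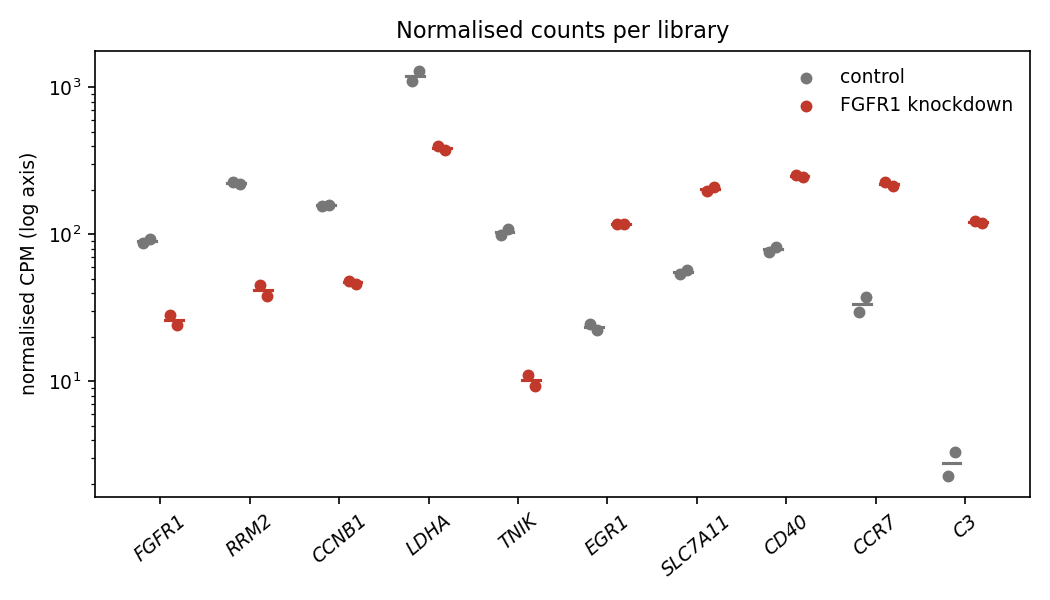
Normalised CPM on a log axis for 10 named genes, with a point per library (2 control in grey, 2 knockdown in red) and a line at each group mean. Both knockdown points of FGFR1, RRM2, CCNB1, LDHA and TNIK lie below both control points, and those of EGR1, SLC7A11, CD40, CCR7 and C3 lie above.

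The list fixed for fibroblast growth factor signalling leaves out some ligands of the family and holds 2 fusion partners of FGFR1, FGFR1OP and FGFR1OP2, which are not family members. Of its 12 genes tested, 2 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.581). The docking protein gene FRS2 rose by 0.61 on the log2 scale (SE 0.12), FGF11 by 3.35 (SE 0.68, from 3 and 9 counts to 60 and 47, and 4.32 without control library 2), and FGFR1OP fell by 0.53 (SE 0.13), so that both falls were of the fusion partners. None of the 12 passed without knockdown library 1 or without knockdown library 2, where the edgeR Benjamini-Hochberg adjusted p was 0.0772 and 0.106 for FRS2, 0.132 and 0.0872 for FGF11, and 0.120 and 0.186 for FGFR1OP, and 4 rose without either control library. With upper-quartile scaling 3 rose and 0 fell, and with library totals 3 rose and 1 fell (edgeR Benjamini-Hochberg adjusted p of FGFR1OP with upper-quartile scaling 0.0683). Of 22 target genes of the ERK pathway, which acts below the receptor, 8 rose and 4 fell, with 8 and 5 adjusted over the list alone. EGR1, an immediate early transcription factor gene, rose 5.04-fold (log2 2.33, SE 0.10), and DUSP5, a phosphatase of ERK, rose 2.40-fold (log2 1.26, SE 0.13). SPRY1, an inhibitor of the pathway, had a log2 change of -2.23 (SE 0.67), which was -1.64 without knockdown library 1 and -3.21 without knockdown library 2, with edgeR Benjamini-Hochberg adjusted p of 0.247 and 0.0800, and 0.0696 with the longest transcript. The camera adjusted p of the ERK list was 0.0557, but 0.0129 without control library 1, 0.0439 with upper-quartile scaling, 0.0486 with library totals and 0.0468 with the filter of 1 CPM, and fry gave 0.0333. In the ERK list 4 members rose and 1 fell without either knockdown library.

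Of 27 NF-kB target genes 19 rose and 1 fell, with 19 and 2 adjusted over the list alone (median log2 0.79; camera adjusted p = 2.64e-10, and adjusted p = 0.258 with an estimated correlation). CD40, a costimulatory receptor, rose 3.16-fold (log2 1.66, SE 0.08) and the adhesion molecule gene ICAM1 rose 2.60-fold (log2 1.38, SE 0.07). SOD2, a mitochondrial antioxidant enzyme, fell by 0.70 (SE 0.14), with an edgeR Benjamini-Hochberg adjusted p of 0.0661 and 0.102 without knockdown library 1 or 2. Of 10 MHC class II genes 7 rose and 0 fell, also adjusted over the list alone (median 0.87; camera adjusted p = 8.41e-05, and adjusted p = 0.265 with an estimated correlation), among them HLA-DQB1 (log2 1.06, SE 0.08) and HLA-DOA (log2 2.59, SE 0.26; edgeR Benjamini-Hochberg adjusted p = 0.0826 with the longest transcript). With the longest transcript 4 of 8 class II genes rose, and without genes that have copy rows only 3 were left, all higher, with a median of 0.59. Of 37 interferon-stimulated genes 16 rose and 0 fell, also adjusted over the list alone (median 0.45; camera adjusted p = 8.18e-05, and adjusted p = 0.266 with an estimated correlation). They included the RNA sensor gene IFIH1 (log2 1.46, SE 0.09) and IFIT2 (log2 1.76, SE 0.14), and 10 and 8 rose without knockdown library 1 or 2, while 3 fell without either control library. Of 26 B cell identity genes 9 rose and 5 fell, with 10 and 5 adjusted over the list alone, and 8 fell without control library 1 and 3 without knockdown library 1. The camera adjusted p of that list was 0.0327, with a median of only 0.08, and was 0.0538 without control library 1, 0.139 without knockdown library 1, 0.127 with limma-voom, 0.304 without a filter and 0.0606 with the replicate block, and the adjusted p was 0.431 with an estimated correlation. CIITA, the master regulator of MHC class II, rose by 1.16 (SE 0.07), and the transcription factor gene BACH2 fell by 2.49 (SE 0.44; edgeR Benjamini-Hochberg adjusted p = 0.0502 without knockdown library 1).

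Other B cell lists held changes both ways and were not called by camera. Of 24 genes of B cell receptor signalling 6 rose and 8 fell, with 7 and 9 adjusted over the list alone (camera adjusted p = 0.826), such as the complement receptor gene CR2 (log2 1.36, SE 0.09) and the kinase gene SYK (log2 -1.05, SE 0.11). Without knockdown library 1 or 2, 2 and 3 of them rose and 3 and 1 fell, and 13 fell without control library 1. With upper-quartile scaling 8 rose and 3 fell, and with library totals 8 and 5, so which way most calls went rested on the scaling. Of 18 genes tied to mantle cell lymphoma 4 rose and 6 fell, with 4 and 7 adjusted over the list alone (camera adjusted p = 0.782). BIRC3, an inhibitor of apoptosis, rose by 1.29 (SE 0.07) and the histone methyltransferase gene WHSC1 fell by 0.81 (SE 0.08), with 2 rising without either knockdown library and 2 and 3 falling without knockdown library 1 or 2. Of 16 plasma cell genes 5 rose and 2 fell, with 5 and 3 adjusted over the list alone (camera adjusted p = 0.746). IGJ, the joining chain of antibodies, rose by 1.24 (SE 0.11) and TNFRSF17 fell by 1.91 (SE 0.28), with 2 and 1 rising and 1 falling without knockdown library 1 or 2, 7 falling without control library 2 and 5 falling without a filter. Of 22 chemokine receptor and adhesion genes 8 rose and 6 fell, with 8 and 7 adjusted over the list alone (camera adjusted p = 0.924), and 4 rose without either knockdown library. CCR7, a homing receptor for lymph nodes, rose 6.55-fold (log2 2.71, SE 0.13).

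Of 17 FOXO target genes tested 7 rose and 4 fell, with 8 and 4 adjusted over the list alone (camera adjusted p = 0.582). The insulin receptor gene INSR rose by 1.02 (SE 0.08). FOXO1 itself had a log2 change of -2.75 (SE 0.54), which was -2.12 without control library 1, and its edgeR Benjamini-Hochberg adjusted p was 0.0669 and 0.0652 without knockdown library 1 or 2. The median of the list was -0.17, while its mean and the camera direction were positive, and the median turned positive with upper-quartile scaling. Without knockdown library 2, 4 members rose, 1 and 2 fell without knockdown library 1 or 2, and 7 fell without control library 2.

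Of 79 nuclear genes of the respiratory chain 65 fell and 2 rose, with 68 and 2 adjusted over the list alone (median log2 -0.83; camera adjusted p = 3.42e-19, and adjusted p = 0.0703 with an estimated correlation). NDUFS5 of complex I fell by 1.45 (SE 0.08), and COX7B of cytochrome c oxidase fell by 1.31 (SE 0.09). ATP5S rose by 0.66 (SE 0.17), with an edgeR Benjamini-Hochberg adjusted p of 0.258 and 0.0794 without knockdown library 1 or 2, and no member rose without either. Of 22 glycolysis genes 13 fell and 3 rose, also adjusted over the list alone (median -0.49; camera adjusted p = 3.95e-05, and adjusted p = 0.367 with an estimated correlation), and 1 rose without either knockdown library. LDHA, which makes lactate, fell from 1201 ± 130.6 to 386.0 ± 15.8 CPM (SD, n = 2 each), PGAM1 fell by 1.26 (SE 0.08), and ALDOC rose by 1.23 (SE 0.16). Of 30 hypoxia response genes 11 rose and 8 fell, with 11 and 9 adjusted over the list alone, and 4 rose without either knockdown library. Camera did not call the list (adjusted p = 0.924, with a positive direction where fry gave a negative one), and the lipoprotein receptor gene VLDLR rose 2.83-fold. Of 28 genes of cholesterol and lipid synthesis 14 fell and 3 rose, with 15 and 3 adjusted over the list alone (median -0.34; camera adjusted p = 0.00242, and adjusted p = 0.265 with an estimated correlation). LSS, which forms lanosterol, rose by 1.12 (SE 0.08).

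Genes of the amino acid and integrated stress response were mostly higher: 22 of 26 rose and 1 fell, with 23 and 1 adjusted over the list alone (median log2 0.78; camera adjusted p = 1.32e-13, and adjusted p = 0.141 with an estimated correlation). SLC7A11, the cystine transporter gene, rose 3.68-fold (log2 1.88, SE 0.09), and PPP1R15A, which directs dephosphorylation of eIF2-alpha, rose 3.26-fold (log2 1.71, SE 0.08). PSPH, an enzyme of serine synthesis, fell by 0.33 (SE 0.10), with an edgeR Benjamini-Hochberg adjusted p of 0.0345 that became 0.182 and 0.302 without knockdown library 1 or 2, 0.242 and 0.149 with upper-quartile scaling and library totals, 0.0765 with the replicate block, 0.0759 with summed transcripts and 0.0876 with DESeq2. In the ER chaperone and heat shock lists more genes fell than rose. Neither list holds HSPA6, which rose by 6.02 on the log2 scale (SE 0.40). Of 17 ER chaperone genes 11 fell and 5 rose, also adjusted over the list alone (median -0.80; camera adjusted p = 0.0160, adjusted p = 0.0800 with limma-voom, and adjusted p = 0.487 with an estimated correlation), with CALR 2.27-fold lower, HERPUD1 3.12-fold higher, and 3 rising without either knockdown library. Of 14 heat shock genes 10 fell and 1 rose, with 11 and 1 adjusted over the list alone (median -0.70; camera adjusted p = 4.19e-05, and adjusted p = 0.309 with an estimated correlation). HSPA8 fell by 1.51 (SE 0.09), HSP90AA1 fell by 1.08 (SE 0.08), and DNAJB1 rose by 1.07 (SE 0.09), with 2 and 3 rising without control library 1 or 2.

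With all 4 libraries most genes of the MYC and nucleolar list fell, while most ribosomal protein genes rose. These lists were not tested against each other, and the first also holds genes outside ribosome assembly, such as NME1 and ODC1. Of 27 MYC and nucleolar genes 18 fell and 0 rose, also adjusted over the list alone (median log2 -0.55; camera adjusted p = 2.06e-07, and adjusted p = 0.266 with an estimated correlation), and 11 fell without knockdown library 2. NME1, a nucleoside diphosphate kinase, fell by 1.57 (SE 0.10), and ODC1, the enzyme that starts polyamine synthesis, was 2.29-fold lower. Of 78 ribosomal protein genes 56 rose and 1 fell, with 60 and 1 adjusted over the list alone (median 0.46; camera adjusted p = 1.42e-11, and adjusted p = 0.309 with an estimated correlation). RPL3 rose from 1212 ± 19.9 to 2379 ± 6.79 CPM (SD, n = 2 each) and RPL31 rose by 1.04 (SE 0.07). RPL39L fell by 0.84 (SE 0.22), with an edgeR Benjamini-Hochberg adjusted p of 0.175 and 0.0512 without knockdown library 1 or 2, and 26 and 27 ribosomal protein genes rose without those libraries. Ribosomal protein genes took 5.88% and 6.14% of counts in the controls and 9.18% and 9.35% after knockdown.

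**Figure D3:**
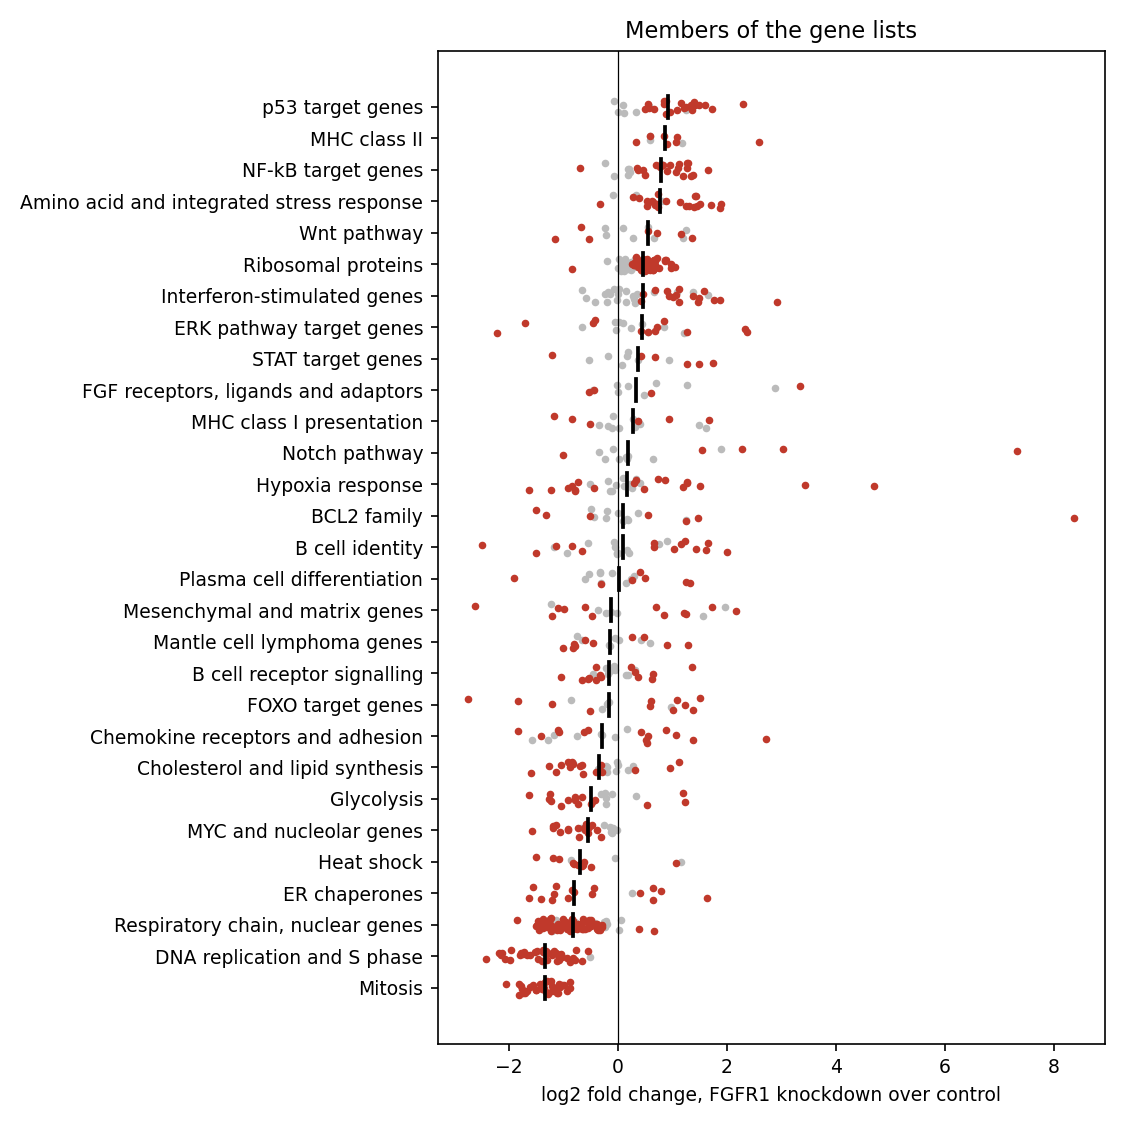
Log2 fold change of knockdown over control (horizontal axis) for each tested member of the gene lists (vertical axis), with genes at an adjusted p below 0.05 in red, other genes in grey and the list median as a black line. Points of the S phase and mitosis lists lie left of 0 around medians of -1.34 and -1.35, and those of p53 target genes lie mostly right of 0 around 0.92. HEYL and HRK, the farthest points of the Notch and BCL2 lists, had 0 counts in both controls, so their place is not a bound.

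The remaining lists were not called by camera: STAT targets (adjusted p = 0.0667, but 0.0126 and 0.0457 without control library 1 or 2, 0.0475 with limma-voom, 0.0468 with the filter of 1 CPM and 0.00534 with fry), Notch (0.0966, and 0.0312 without control library 1), Wnt (0.581), MHC class I presentation (0.826), mesenchymal and matrix genes (0.826) and small noncoding RNAs (0.113, and 0.0264 without knockdown library 1 and 0.0406 with limma-voom). The class I list had a median of 0.28 and a negative camera direction, and the mesenchymal list a median of -0.13 and a mean of 0.13. The most abundant small noncoding RNAs, RPPH1 and RMRP, had log2 changes of -0.16 (SE 0.21) and 0.19 (SE 0.37). Markers of other cell types were mostly at low counts. In the stromal and epithelial list COL1A1 rose from 11.9 ± 5.09 to 66.8 ± 4.60 CPM and CDH1 from 4.85 ± 1.37 to 23.4 ± 1.27 CPM (SD, n = 2 each), 2 of the 4 members tested, and the band 3 gene SLC4A1 rose by 2.91 on the log2 scale (SE 0.36), 1 of 3 erythroid members tested, while ALAS2 had a log2 change of 0.84 (SE 0.55). Of 3 T and NK cell markers 0 passed the edgeR test, and PRF1 and CD4 had log2 changes of -0.29 (SE 0.41) and 1.29 (SE 0.71). Of 5 myeloid markers 1 rose and 1 fell, and camera did not call the list (adjusted p = 0.826). ITGAM, the most abundant, had a log2 change of -0.14 (SE 0.09), and 0.0223 with upper-quartile scaling. VCAN fell by 0.34 (SE 0.10), with an edgeR Benjamini-Hochberg adjusted p of 0.0374 that became 0.0561 without control library 2 and 0.245 and 0.232 without knockdown library 1 or 2, and was also above 0.05 with median-of-ratios (0.0530), upper-quartile (0.246) and library-total scaling (0.157), DESeq2 (0.0889), summed transcripts (0.0670) and the replicate block (0.0699). In all, 0 myeloid markers passed without either knockdown library.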

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

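The alternatives with summed transcripts, with the longest transcript and without genes that have copy rows were chosen only after the data were seen. FGFR1 kept its fall and its call under every alternative run, with log2 changes from -1.61 to -1.89. The number of changed genes was 5853 to 6977 under the alternatives that kept all 4 libraries and tested against no change, and 2215 (1122 higher, 1093 lower) in the glmTreat test against 1.5-fold, which asks for a larger change. The replicate block gave 5853 genes. The libraries share only a number (correlation of deviations -0.094), and groups of 2 allow no count of other splits. Without 1 library at a time the number ran from 2678 to 9505, with 1053 to 4848 higher and 1585 to 4730 lower. The fits without a control library rest on the spread of the knockdown pair and those without a knockdown library on that of the control pair. Of 16 lists called, 0 were called with an estimated correlation. That version has only 2 residual degrees of freedom, so it does not tell stable lists from unstable ones. Fry called each of the 16 except the histone list, with adjusted p of 0.0271 or below. Some medians and genes, all without a call in any of these settings, changed sign, and the cause was not tested. With upper-quartile scaling the medians were 0.0075 for FOXO targets, 0.0038 for B cell receptor signalling, 0.013 for mantle cell lymphoma genes and 0.041 for mesenchymal genes (0.0081 with library totals), and RPPH1 and ITGAM were at 0.010 and 0.022. Without a filter the FOXO and mesenchymal medians were 0.60 and 0.70, and with the filter of 1 CPM the FOXO median was 0.23. The MHC class I median was -0.012 with the longest transcript and -0.23 without copy rows. Without 1 library at a time the medians ran from -0.18 to 0.46 for FOXO targets, from -0.010 to 0.25 for hypoxia and from -0.16 to 0.31 for myeloid markers, RPPH1 from -0.36 to 0.10, RMRP from -0.27 to 0.62 and PRF1 from -0.56 to 0.049.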

Other observations

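The 14 further gene lists and the genes singled out here, other than FGFR1, COL1A1, CDH1 and SLC4A1, were chosen only after the values were seen, and so were the tests of sequencing depth, independent molecules, scaling, length and GC content, and vector differences. Of 37 proteasome subunit genes 34 fell and 0 rose (median log2 -0.84), as did 19 of 22 genes of condensin, cohesin and related SMC complexes (median -0.96), 28 of 34 genes of RNA-binding hnRNP and SR proteins (median -0.78) and 11 of 13 chaperonin and prefoldin genes (median -0.76). Of 26 genes of Fanconi anaemia and homologous recombination 21 fell and 1 rose (median -0.83), of 76 mitochondrial ribosomal protein genes 52 fell and 1 rose (median -0.65; 24 and 25 fell without knockdown library 1 or 2), of 31 kinesins 16 fell and 5 rose (2 rose without either knockdown library) and of 25 tubulins 12 fell and 2 rose (7 fell without either knockdown library, and 1 rose without knockdown library 2). TUBA1B fell by 2.36 on the log2 scale (SE 0.12), TUBB3 rose by 2.14 (SE 0.36; edgeR Benjamini-Hochberg adjusted p = 0.00446, and 0.0553 without knockdown library 2) and SMC2, a condensin subunit, fell by 1.53 (SE 0.07). Camera called each of these 8 lists, with adjusted p from 6.27e-15 to 9.02e-05, and with an estimated correlation the adjusted p was 0.120 to 0.136.

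Of 11 complement genes 9 rose and 1 fell (median log2 1.36; camera adjusted p = 4.60e-09, and adjusted p = 0.136 with an estimated correlation). Of 17 checkpoint and costimulatory ligand and receptor genes 8 rose and 1 fell, with 3 falling without control library 1 (camera adjusted p = 0.000686, and adjusted p = 0.136 with an estimated correlation). CD274, which encodes the checkpoint ligand PD-L1, rose from 31.2 ± 1.14 to 135.7 ± 6.36 CPM and CD80 from 26.2 ± 3.81 to 70.7 ± 2.33 CPM (SD, n = 2 each). CD86, the partner of CD80, and CD70 had log2 changes of -0.59 (SE 0.24) and 0.42 (SE 0.17), with edgeR Benjamini-Hochberg adjusted p of 0.0923 (3.02e-06 to 0.378 over the alternatives) and 0.102 (2.37e-11 to 0.360). MYC rose by 0.43 on the log2 scale (SE 0.12; edgeR Benjamini-Hochberg adjusted p = 0.0329, and 0.131 and 0.181 without knockdown library 1 or 2). CCND1, the cyclin gene activated in mantle cell lymphoma, had 1208 ± 363.2 CPM in the controls and 760.4 ± 58.1 CPM after knockdown (SD, n = 2 each). Its edgeR Benjamini-Hochberg adjusted p was 0.0561, and over the alternatives it ran from 4.52e-18 to 0.258. It was 0.0398 with median-of-ratios scaling, 0.0482 with limma-voom, 0.0351 with the replicate block and 0.000855 with DESeq2. Without control library 1 or 2 it was 0.000131 and 4.52e-18, with log2 changes of -0.33 and -0.92, and without knockdown library 1 or 2 it was 0.258 and 0.177. Camera did not call genes of cytosolic tRNA synthetases (adjusted p = 0.141, and 0.00648 without control library 2), translation factors (0.567), lysosomal proteins (0.978) or autophagy (0.240).

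MIR30A, a microRNA gene, had 0 counts in both controls and 3510 and 3246 after knockdown, 1310-fold higher against 3 counts per library. Its host transcript LINC00472 and its neighbour MIR30C2 together reached at most 0.0308% of that count, which speaks against induction of the locus. The other MIR30 genes together reached at most 0.801%, each with at most 16 counts in any library. Reads from a short hairpin vector built on a miR-30 backbone would give this, but so would a rise of MIR30A alone. The share of the other MIR30 genes does not separate these explanations, while the low host and neighbour counts speak against a rise from the locus. Such a vector is a candidate explanation that was not tested. The labels name no vector, and no read sequences were analysed here.

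Both knockdown libraries detected more genes than both controls, and 113 genes had 0 counts in both controls and at least 10 in both knockdown libraries, against 1 the other way, which the tables do not put down to depth, since after thinning every library to 18280864 counts the gap was still 1958 genes. Cells of another type stay open: at most 16.7% of a marker list rose, under the bound set beforehand, but that bound counted members with too few reads to be called, and only 15 of 58 were tested, so it decides nothing. COL1A1, CDH1 and SLC4A1 rose, and COL1A2 and COL3A1 reached at most 8 counts in a knockdown library beside 1328 and 1347 of COL1A1. Families silent in B cells, such as olfactory receptors, were 1.82 times higher in the lowest knockdown than in the highest control library, between the bounds set beforehand, so genomic DNA or unspliced RNA stays open. The control pair had a median variance-to-mean ratio 2.26 times that of the knockdown pair at 5 to 20 counts, past the bound of 2 first set for fewer independent molecules in the controls, but knockdown libraries thinned by the pooled ratio of 1.97 still detected 18805 and 20460 genes (a condition added after that ratio was seen), and a larger spread between control cultures could raise the ratio too, so the 2 cannot be told apart.

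The fall of cell cycle genes was set against 3 explanations other than FGFR1 loss. Across 3 other scalings the higher of the S phase and mitosis medians was at most -1.18. Those scalings left the median of all genes at 0.026 to 0.17 on the log2 scale, so they could hardly have removed a fall of this size. They show only that the fall does not rest on the choice among them. After a trend on transcript length and GC content was removed the higher median was -1.48, so length and GC content do not account for the fall. A vector or selection difference cannot be told apart from the loss of FGFR1, because 0 control libraries had a MIR30A count and the groups may differ in what they carry as well as in FGFR1. The loss of FGFR1, named by the design, stays open as a hypothesis. A control with the same vector would bear on the vector or selection difference alone.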
